A study of Chlamydomonas reinhardtii with 12 samples.

How the data were processed

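Total RNA of Chlamydomonas reinhardtii, a unicellular green alga, from a strain labelled npq4, was measured on 12 Agilent two-colour arrays. Per the labels, cells were grown in an acetate medium with or without sulfur in a sealed bioreactor, and the Cy3 channel of each array held RNA of 0 h while the Cy5 channel held RNA of 24, 48, 72 or 96 h. Each time had 3 arrays, numbered as biological replicates 1 to 3. The files place the 4 arrays of each replicate on 1 slide, so slide and replicate are the same factor. The slide of replicate 1 was scanned in another session than those of replicates 2 and 3. The dyes were never exchanged, so an effect of dye on a gene stays in each ratio over 0 h and cancels in differences between times.

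Spot intensity values were produced by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. They hold the median signal of each spot and of its local background, with no further correction. Processed signal intensity, also deposited, was background-subtracted and dye-normalized by the same software, per the file headers. The deposited log10 ratio is Cy5 over Cy3 of the processed signals in most spots. It was set to 0 in 5.36 to 36.6% of spots per array. The series value table holds a score that the authors gave without a stated scale. Set against the scanner values of the same arrays it was the log10 ratio multiplied by 1e+09 and rounded, with the same direction and no further centring. Its column medians on the log2 scale were 0, except -0.017 for the 48 h array of replicate 2.

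The array held 45218 spots, of which 43801 were no controls. They carried 43705 distinct probes of 14562 gene models, nearly all with 3 probes. The files name probes by the number of a gene model of an older gene set. These numbers were matched to the older locus tags of a RefSeq gene table of assembly Chlamydomonas_reinhardtii_v5.5, and 12304 gene models matched. The builds differ, so no coordinates are given, and the table served only for locus tags and for which loci are neighbours. Its symbol column repeats the locus tag. Genes are therefore named by locus tag, and no function is given. Of the entries of 23 gene lists fixed by symbol, 0 could be found, so the tests of gene lists, the markers of gametes and the genes chosen by symbol, among them the check of the strain, were not run.

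Mean signals were not among the columns, so the median signals were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. Log2 ratios were normalized by loess within each array, with control spots and outlier spots at weight 0. Outlier spots were then left out, and saturated spots were kept. Spots of a probe were averaged. A probe was kept when it was well above background in either channel on at least 3 arrays, which 35747 probes were, and when at most 2 arrays lacked a value. The probe with the highest mean intensity stood for its gene model. This left 14080 gene models, 11907 of them with a locus tag. Between 40.9 and 79.8% of spots were well above background in Cy3 and between 36.5 and 83.7% in Cy5. On the arrays of replicate 1 several spots shared the highest value of a channel and were taken as saturated, 216 to 765 per array in Cy5 and 181 to 262 in Cy3. The deposited saturation marks held those in Cy5 and 0 of those in Cy3. The other replicates had 0 saturated spots. A ratio with 1 channel saturated is understated or overstated, and one with both saturated has a fixed value. The number of arrays limits the precision.

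A mean per time was fitted over all 12 arrays with limma (lmFit and eBayes). Ratios over 0 h, differences between times and a moderated F test among the times were called at a Benjamini-Hochberg adjusted p under 0.05. Named loci were the 5 highest and the 5 lowest mean log2 ratios at each time among called loci that changed at least 2-fold and in the same direction in all 3 replicates. The same rule for 96 h minus 24 h named 0 loci. The tests, alternatives and this rule were chosen before the data were examined, with 1 change to the rule. As planned it asked for a gene symbol or descriptive name, and since none could be matched, a locus tag was taken in its place. Leaving out the 48 h array of replicate 3, leaving out saturated spots (with the tested probes kept or replaced) and weighting the arrays were chosen after. Arrays with the same replicate number deviated together from the means of their times. Every such pair correlated across gene models, with r from 0.298 to 0.95, so arrays of a replicate are not independent. Each replicate is also 1 slide, so pairing of the samples and an effect of the slide cannot be told apart. The fit with the replicate as a block used a random block for ratios over 0 h (estimated correlation 0.459) and a fixed block for differences between times.

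The fit was tested on simulated data for 14080 gene models with the measured spreads and that correlation, in 10 draws with 200 gene models changed at 96 h. For 96 h against 0 h it called 53.1% of those changed by 1 on the log2 scale, 80.1% of those changed by 2 and 95.0% of those changed by 4. Of its calls 10.4% were unchanged gene models, above the 5% that the threshold aims at. The fit takes no account of the correlation within replicates, but whether that is the whole cause was not tested. The share was 6.99% with the random block and 2.89% when only the 3 arrays of 96 h were fitted. For 96 h minus 24 h it was 1.13% without a block and 6.94% with the fixed block. The simulated spreads were normal and alike at all times. With only 3 arrays, simulated changes were called where the real data gave 0 calls. These shares may therefore not hold for the real data.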

Results

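Transcript levels of a strain labelled npq4, a label that was not checked against the data, were measured at 24, 48, 72 and 96 h against 0 h, with 3 biological replicates per time, in a study of hydrogen production under sulfur starvation. The labels name a medium with or without sulfur and do not give the sulfur status of each time. Each of the 12 arrays compared 1 later time in Cy5 with 0 h in Cy3. In all, 14080 gene models were tested. Values are log2 ratios over 0 h with the SD over 3 replicates, and adjusted p-values are from limma.

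At 24 h CHLRE_13g585550v5 stood at 5.99 ± 1.36 (SD, n = 3; adjusted p = 0.00609). Its probe was saturated in Cy5 on the array of replicate 1. Without that replicate the value was 6.695, without replicate 2 it was 5.34, and over all its probes it was 4.90. CHLRE_06g284200v5 stood at 5.34 ± 0.15 (SD, n = 3; adjusted p = 0.008). CHLRE_06g288550v5, CHLRE_09g386986v5 and CHLRE_13g582600v5 had mean log2 ratios of 4.77, 4.60 and 4.32. CHLRE_10g463350v5 stood at -3.87 ± 0.93 (SD, n = 3; adjusted p = 0.00609). CHLRE_06g309000v5, CHLRE_02g094250v5, CHLRE_10g452800v5 and CHLRE_03g164000v5 had mean log2 ratios of -3.65, -3.29, -3.20 and -3.16. The value of CHLRE_06g309000v5 was -4.73 without replicate 1 and -2.77 without replicate 2, and that of CHLRE_13g582600v5 was 3.36 without replicate 2. All 10 loci had the same direction in each replicate, as the rule for naming them required. In replicate 1, CHLRE_06g284200v5, CHLRE_09g386986v5 and CHLRE_13g582600v5 were saturated in Cy5 and CHLRE_03g164000v5 in Cy3. Over all probes CHLRE_06g284200v5 (5.49) and CHLRE_09g386986v5 (5.32) were above CHLRE_13g585550v5. With the saturated spots left out and the tested probes kept, CHLRE_06g284200v5, CHLRE_13g582600v5 and CHLRE_03g164000v5 were not called on their 2 other arrays, with log2 ratios of 5.43, 4.90 and -3.66 (adjusted p = 0.0542, 0.149 and 0.0653). For CHLRE_13g582600v5 the other 2 probes did not follow, with mean log2 ratios of -0.415 and -0.004. In CHLRE_06g288550v5, CHLRE_10g463350v5, CHLRE_06g309000v5 and CHLRE_10g452800v5, 1 other probe lay near 0, at 0.33, -0.13, -0.25 and -0.37. Over all probes these loci were at 2.88, -2.22, -2.09 and -2.23. Both other probes of the remaining named loci lay further from 0, the closest at -1.69 for CHLRE_03g164000v5. With the replicate as a block CHLRE_06g309000v5 was no longer called at 24 h (adjusted p = 0.0506). In all, 169 gene models were higher and 99 were lower at 24 h. When only the 3 arrays of a time were fitted with limma, 0 gene models were called at 24, 48, 72 and 96 h, with smallest adjusted p-values of 0.0934, 0.166, 0.0863 and 0.0669, and 1519, 1636, 1675 and 2018 at an unadjusted p under 0.05.

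At 48 h CHLRE_13g585550v5 stood at 5.02 ± 1.94 (SD, n = 3; adjusted p = 0.0138). CHLRE_09g398993v5 had a mean log2 ratio of 4.28 and CHLRE_06g284200v5 one of 4.18. With the replicate as a block these 2 loci were no longer called at 48 h (adjusted p = 0.0593 and 0.0531). Without the 48 h array of replicate 3, CHLRE_09g398993v5 was not called either (adjusted p = 0.0532). CHLRE_06g309000v5 stood at -4.43 ± 1.17 (SD, n = 3; adjusted p = 0.0165). CHLRE_12g554100v5 and CHLRE_01g010900v5 had mean log2 ratios of -3.53 and -3.28. Over all probes CHLRE_06g309000v5 was at -2.99 and CHLRE_01g010900v5 at -2.67. Without the 48 h array of replicate 3, 8 of the 10 named values of this time moved by over 1.5 times, all to larger ratios, among them CHLRE_13g585550v5 to 5.92, CHLRE_06g284200v5 to 5.26, CHLRE_06g309000v5 to -5.08, CHLRE_12g554100v5 to -4.27 and CHLRE_01g010900v5 to -3.89. Without replicate 2 CHLRE_13g585550v5 was at 3.998. In replicate 1 CHLRE_06g284200v5 was saturated in Cy5 and CHLRE_01g010900v5 in Cy3. With saturated spots left out and the tested probes kept, CHLRE_13g585550v5, CHLRE_06g284200v5 and CHLRE_01g010900v5 were not called on 2 arrays, with log2 ratios of 5.13, 3.65 and -3.06 (adjusted p = 0.0868, 0.164 and 0.148). At this time 125 gene models were higher and 82 were lower. The ratios of replicate 3 were smaller than those of the other replicates for most of these loci, such as 2.02 against 5.24 and 5.28 for CHLRE_06g284200v5.

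At 72 h CHLRE_13g585550v5 stood at 6.76 ± 0.48 (SD, n = 3; adjusted p = 0.00178), saturated in Cy5 in replicate 1. The value was 6.99 on its 2 other arrays and 5.44 over all its probes. CHLRE_06g284200v5 had a mean log2 ratio of 6.15, and CHLRE_13g582600v5 stood at 6.04 ± 0.95 (SD, n = 3). CHLRE_09g391801v5 had a mean log2 ratio of -4.42 and CHLRE_10g463350v5 one of -4.36 ± 0.65 (SD, n = 3). Without replicate 2 CHLRE_06g284200v5 was at 7.02 and CHLRE_09g391801v5 at -3.73. CHLRE_07g332800v5 had the smallest SD of the loci named as lower at this time, at -4.14 ± 0.26 (SD, n = 3; adjusted p = 0.00109). Its other 2 probes lay at -0.28 and 0.14. Over all probes of a gene the log2 ratios at 72 h were -1.43 for CHLRE_07g332800v5, 2.17 for CHLRE_13g582600v5 and -2.42 for CHLRE_10g463350v5. Of the 40 named values 28 moved by over 1.5 times with that mean, 27 of them to a smaller ratio, and all 40 stayed called. The mean includes the tested probe, so a value can stay called when the other probes did not change. In all, 215 gene models were higher and 182 were lower at 72 h.

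At 96 h the counts were 456 higher and 282 lower. CHLRE_13g585550v5 stood at 5.94 ± 0.61 (SD, n = 3; adjusted p = 0.00267), CHLRE_13g582600v5 at 5.58 ± 0.54 (SD, n = 3) and CHLRE_06g284200v5 at 5.57 ± 1.00 (SD, n = 3). CHLRE_12g556228v5 was at 4.73 ± 0.96 (SD, n = 3; adjusted p = 0.0146). It was also called at 72 h (4.29, adjusted p = 0.0282), but was among the 5 highest at 96 h only. At 96 h its other 2 probes lay at 0.365 and 5.05, and over all its probes it was at 3.38. CHLRE_09g391801v5 stood at -4.54 ± 1.38 (SD, n = 3; adjusted p = 0.0164), and at -3.75 without replicate 2. CHLRE_06g309000v5, CHLRE_07g332800v5, CHLRE_10g463350v5 and CHLRE_13g570851v5 had mean log2 ratios of -4.52, -4.49, -4.26 and -4.04. Without replicate 1, within the session in which replicates 2 and 3 were scanned, 2, 0, 9 and 15 gene models were higher and 2, 0, 19 and 25 lower at 24, 48, 72 and 96 h. Without replicate 2 the counts were 5, 11, 64 and 99 higher and 13, 10, 57 and 70 lower. Without replicate 3 they were 210, 190, 234 and 538 higher and 79, 65, 134 and 299 lower. Of the 40 named values 37 lost their call without replicate 1, 30 without replicate 2 and 12 without replicate 3. Each of these fits lost the same number of arrays, so that number alone does not account for the difference between them. Centring on the median in place of loess left 9, 17, 16 and 117 higher and 1, 0, 19 and 17 lower. CHLRE_13g585550v5 and CHLRE_13g582600v5 were saturated in Cy5 on the array of replicate 1 at all 4 times. At 96 h so was CHLRE_06g284200v5, and CHLRE_13g570851v5 was saturated in Cy3 at 72 and 96 h. With saturated spots left out and the tested probes kept, CHLRE_13g582600v5 was called at none of the 4 times, with log2 ratios of 4.90, 4.32, 6.58 and 5.88 on 2 arrays at 24, 48, 72 and 96 h and adjusted p-values of 0.149, 0.187, 0.0571 and 0.0528. When another probe was taken in its place, the log2 ratios were -0.41, 0.37, 0.34 and 0.44.

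**Figure D1:**
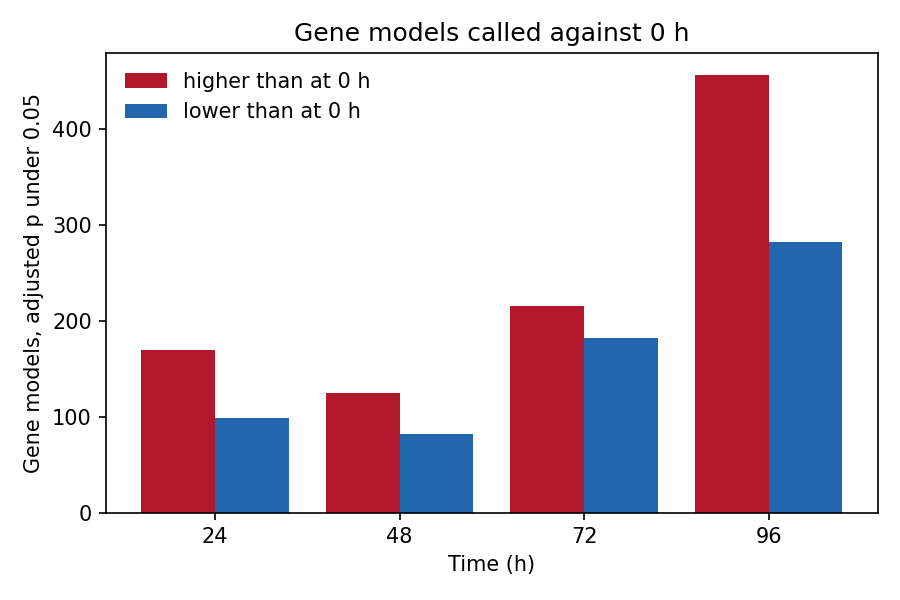
Bars give the number of gene models, on the vertical axis, with an adjusted p under 0.05 at each time in h, higher (red) or lower (blue) than at 0 h. The counts run from 125 to 456 for higher and from 82 to 282 for lower.

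**Figure D2:**
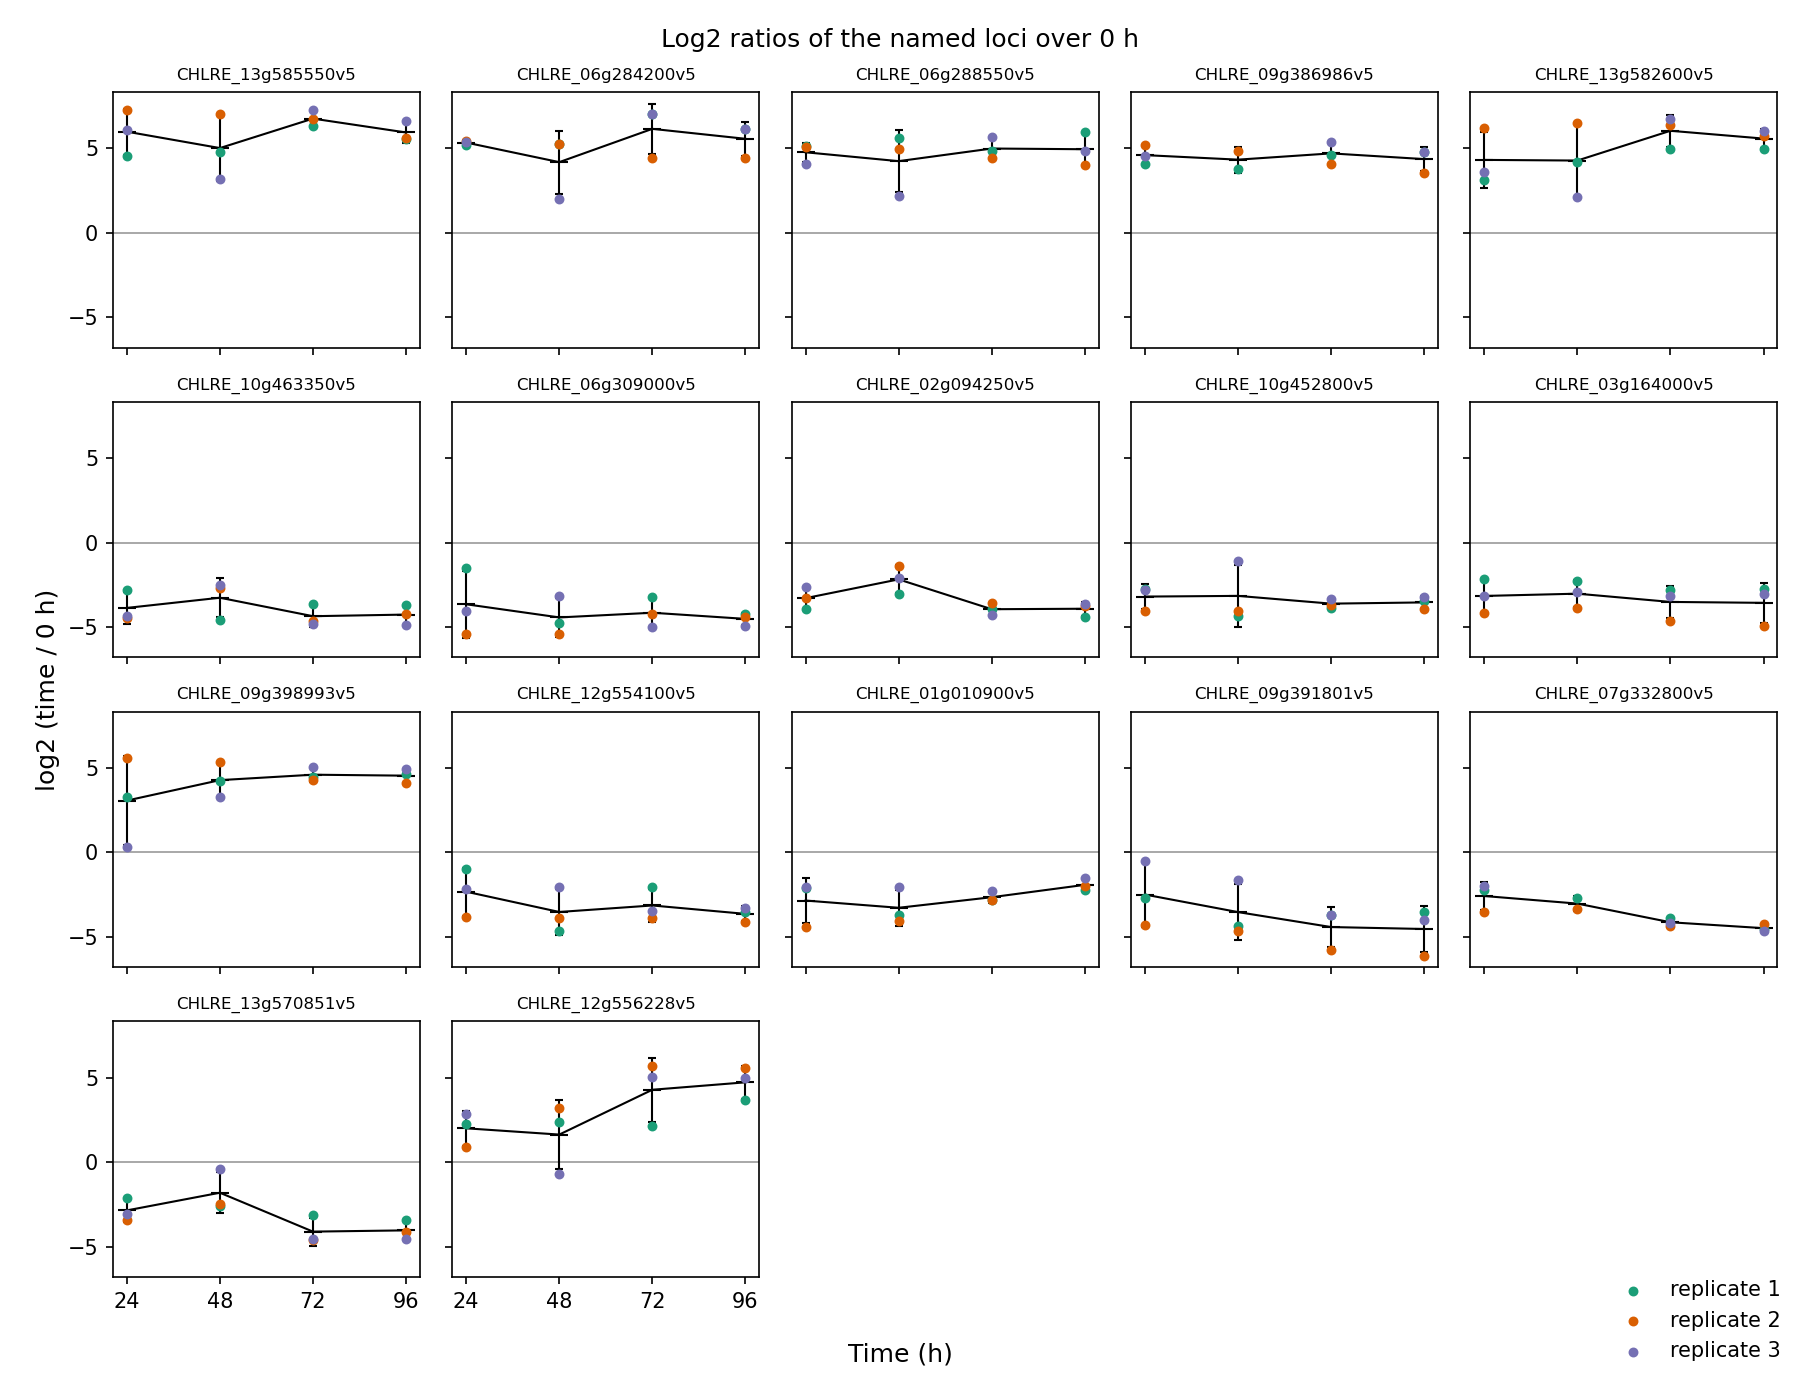
Log2 ratio over 0 h against time in h for the 17 named loci. Coloured points are the 3 replicates, and black marks with bars are their mean and SD (n = 3, but n = 2 at 48 h for CHLRE_09g386986v5 and CHLRE_07g332800v5, which lack replicate 3), such as 6.76 ± 0.48 for CHLRE_13g585550v5 at 72 h.

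Without the replicate as a block, no gene model was called between the times compared. Limma called 0 for 48 h against 24 h, for 72 h against 48 h, for 96 h against 72 h and for 96 h against 24 h, with 95, 166, 10 and 204 gene models at an unadjusted p under 0.05. The unmoderated test also called 0 in each, with 205, 202, 119 and 215 at that unadjusted p. Among the 4 times together the moderated F test called 0, with 123 at an unadjusted p under 0.05. The unmoderated F test called 0 as well, with 161. These fits leave out the correlation within replicates. All of these counts lay far below the 704 that chance alone would give. With the replicate as a fixed block 551, 760, 66 and 1057 gene models lay at an unadjusted p under 0.05. The F test with the block had 807. Of these, 551 and 66 lay below 704 and the others above. Where counts fall far below chance, the p-values are too large. The 0 calls therefore do not show that the times were alike. After adjustment, 2 loci differed between 96 h and 24 h (adjusted p = 0.0366 for both), which are named because they are the only ones. In simulated data with 200 gene models changed, the same fit called 5 to 17 unchanged ones per draw. False calls can grow with the number of true calls, and the case with few changes was not tested. The simulation therefore does not show whether these 2 calls are false. CHLRE_04g221850v5 was at -0.62 ± 0.85 (SD, n = 3) at 24 h and 1.05 ± 1.11 (SD, n = 3) at 96 h. CHLRE_01g047600v5 was at -0.19 ± 0.95 (SD, n = 3) at 24 h and -1.60 ± 0.91 (SD, n = 3) at 96 h.

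At all 4 times 93 gene models were higher than at 0 h and 52 were lower. Of the 17 named loci 11 were called at all 4 times. The calls of 24 h and 96 h shared 154 higher and 85 lower gene models, where independent lists of these sizes would share 5.47 and 1.98. The lists are not independent by the fit itself, since 1 estimate of spread per gene model serves all 4 times. In 20 simulations of unchanged times with the correlation within replicates estimated from these data, at most 0 were shared in either direction. These simulations called at most 2 gene models as higher and 1 as lower over the 4 times, so their 0 says little about the overlap that shared 0 h samples give. The arrays of a replicate are taken here to share 1 sample of 0 h, and these 3 samples cannot be divided into parts of 2. Part of the excess may therefore come from the shared controls. Across gene models, which are not independent replicates, the covariance of the mean log2 ratios of 24 h and 96 h was 0.41 and that of the simulation 0.06. Pearson's r was 0.866, against 0.446 in the simulation. The simulation took the correlation within replicates from these data (0.459), which slide and 0 h sample may both raise. Its r therefore does not show what shared controls alone give.

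Replicate 1 had 608 gene models at least 2-fold higher at all 4 times, replicate 2 had 859 and replicate 3 had 194. At least 2-fold lower were 359, 697 and 253. At 24, 72 and 96 h alone, without the 48 h arrays, the numbers were 685, 918 and 483 higher and 410, 766 and 467 lower. Replicate and slide cannot be told apart. Across gene models, the mean log2 ratio over the 4 times correlated between replicates 1 and 2 with Pearson's r of 0.681. The value was 0.504 for replicates 1 and 3 and 0.326 for replicates 2 and 3. On all 12 arrays 94 gene models were at least 2-fold higher and 45 at least 2-fold lower, against 0.511 and 0.319 if the replicates were independent.

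**Figure D3:**
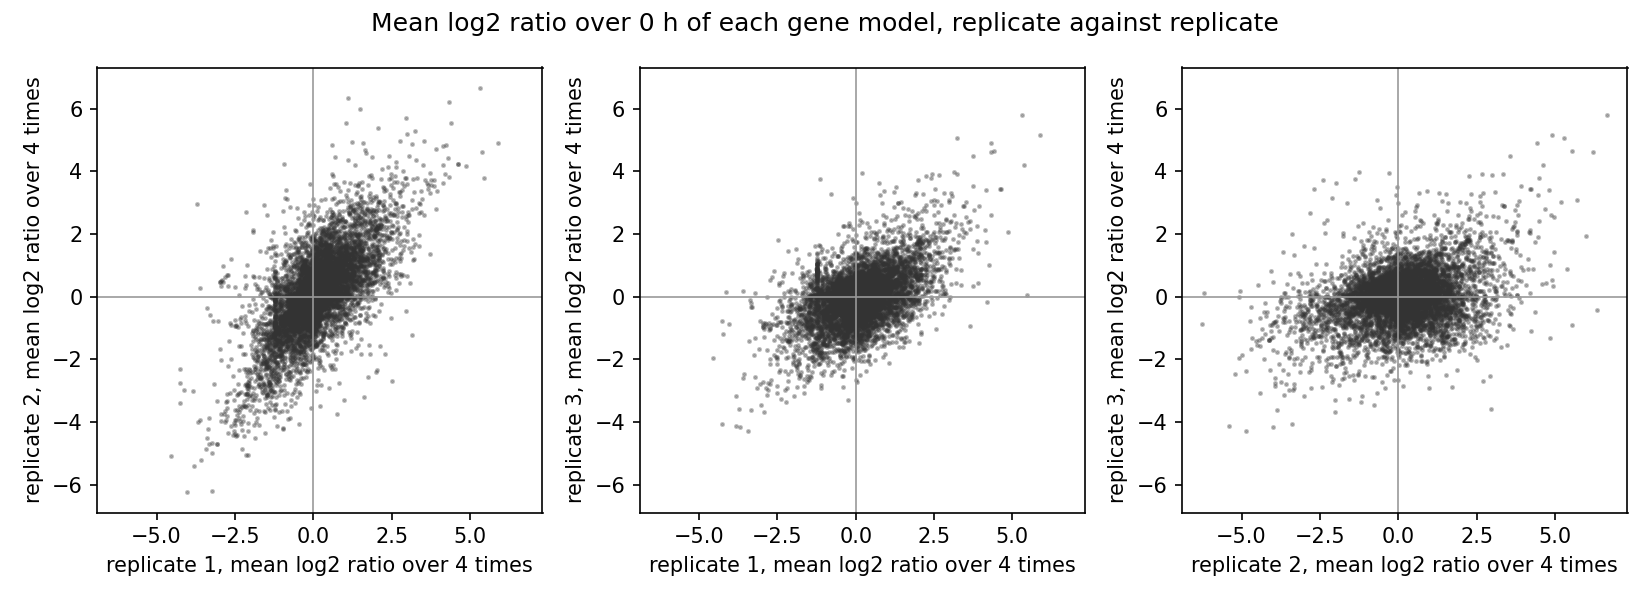
Each point is 1 of 14080 gene models, with its mean log2 ratio over the 4 times in 1 replicate on each axis. The points lie closest to a common line for replicates 1 and 2 (r = 0.681) and least so for replicates 2 and 3 (r = 0.326), and the vertical line at -1.23 in replicate 1 holds 58 saturated gene models.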

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

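The 10 spike-in probes, which the comparisons do not use, gave a median Cy5 signal of at least 640 on every array, against at most 57 for negative control spots. Their median log2 ratio after the dye normalization of Feature Extraction ran from -3.50 to 3.32, so that the highest array exceeded the lowest by 6.82. It ran from -3.50 to 0.464 in replicate 1, from -0.095 to 0.715 in replicate 2 and from 1.12 to 3.32 in replicate 3.

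With the replicate as a fixed block, the log2 difference between 96 h and 24 h was 1.67 for CHLRE_04g221850v5 and -1.41 for CHLRE_01g047600v5. Both differences had the same sign in 3 of 3 replicates. Neither locus was called without the block. In simulated data with 200 gene models changed, the fit with the block called 5 to 17 unchanged ones per draw for this difference. How many it calls when few change was not tested.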

How the results depend on the processing

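Leaving out the 48 h array of replicate 3, leaving out saturated spots and array weights were chosen after the data were seen. Of 720 values of named loci under the alternatives 522 stayed called, 197 did not and 1 reversed. That was CHLRE_13g582600v5 at 24 h, at -0.415 without saturated spots, where another of its probes replaced the saturated one. Leaving out saturated spots in this way also replaced the probe of 174 gene models, so it does not show the effect of saturation alone. With the tested probes kept, 1 of the 40 named values moved by over 1.5 times and 9 were not called, each with 2 arrays. With the mean over all probes of a gene the 40 values stayed called, but 28 moved by over 1.5 times, at most 14.7-fold for CHLRE_13g582600v5 at 72 h. That mean includes the tested probe, so it is no independent check. No count moved by over 1.5 times in either way, and 258, 192, 372 and 713 of the 268, 207, 397 and 738 calls were shared with probes replaced and 250, 179, 355 and 694 with probes kept. The 0 calls between times stayed 0 in the settings that were run for them, except the replicate block, which called 2 for 96 h against 24 h. These comparisons were not run with the mean over all probes of a gene, nor the F test on only the arrays compared. The block moved no count against 0 h by over 1.5 times, and 3 named values lost their call with it. When only the 3 arrays of a time were fitted, and by the unmoderated test, 0 were higher and 0 lower at each time, with 1519, 1636, 1675 and 2018 at an unadjusted p under 0.05 by limma and 1049, 1146, 861 and 1271 by the other. In simulated data for 96 h against 0 h, that fit of 3 arrays called 1.19% of the changes of 1, 42.1% of the changes of 2 and 73.0% of the changes of 4 on the log2 scale. The median log2 ratio of the calls at 96 h was 1.79 for higher and -1.72 for lower. If the simulation matched the real data, some of these calls would be expected with 3 arrays, but 0 were made. Either the number of arrays is not the only cause, or the simulation does not match the real data. Its spreads were normal and alike at all times. Which of the causes holds was not tested. The fit over all 12 arrays had 10.4% unchanged gene models among its simulated calls.

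Median centring in place of loess gave 9, 17, 16 and 117 higher and 1, 0, 19 and 17 lower at 24, 48, 72 and 96 h. The higher share was then 90, 100, 45.7 and 87.3% of calls, against 63.1, 60.4, 54.2 and 61.8%, and the median of all gene models moved to 0.08, 0.23, 0.05 and 0.15. The causes were not tested. Testing every probe gave 273, 225, 338 and 893 higher and 171, 152, 345 and 622 lower, since a gene model then counts up to 3 times. Processed signals gave 472 higher and 446 lower at 72 h. The series value table gave 536 higher and 423 lower at 72 h and 424 lower at 96 h. Array weights gave 438 higher at 72 h and 155 and 348 lower at 24 and 72 h. Without the 48 h array of replicate 3, 272 were higher at 24 h and 54 lower at 48 h. Of the 268, 207, 397 and 738 calls at 24, 48, 72 and 96 h, that fit shared 260, 130, 377 and 699 in the same direction. The cause was not tested for these changes either.

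Leaving out 1 replicate gave ranges of 2 to 210, 0 to 190, 9 to 234 and 15 to 538 higher, and 2 to 79, 0 to 65, 19 to 134 and 25 to 299 lower, at 24, 48, 72 and 96 h. The lowest came without replicate 1 and the highest without replicate 3. Each of these fits lost the same number of arrays, so fewer arrays alone do not account for the low counts. Of the 40 named values 5, 8 and 8 moved by over 1.5 times without replicate 1, 2 and 3, and 37, 30 and 12 lost their call. Median centring moved 20 of them, and processed signals and the series value table each moved 5. The order of the named loci within a time changed with the setting. Tests of gene lists by camera, with an estimated correlation and by fry were not run, since no symbols could be matched. Weak signal over background limits the ratios of dim probes.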

Other observations

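The predictions of the tests below were written before their values were seen. The rule for excluding an explanation was relaxed after they were seen, for all tests with an interval alike. It first asked that the whole interval pass the bound written against the explanation, and now asks that the value pass it and that the interval exclude what the explanation predicted. This changed the reading of 1 test, that of noise of single probes. The interval by genes in that test was also added after. Labels of 0 h and of the sampled time can be exchanged within replicates in only 4 ways, too few for a share under 0.05. The 4 totals of calls against 0 h were 268, 207, 397 and 738, reached in 1 of the 4 exchanges each, and the highest of the others was 0 at every time. The 10 splits of the 6 arrays of any 2 times are likewise too few. Between times the real count was 0, which all 10 splits, and all 100 permutations among the 4 times, reach by construction, so they say nothing about chance. The highest other count was 7 between 48 h and 24 h, and 0 between the other pairs and among the 4 times.

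Of the calls in 1 direction at all 4 times, with no exchange of dyes, a dye effect specific to the probe is a candidate explanation. It predicted that under 0.6 of the other measured probes of these 145 gene models would show the same sign and at least 0.5 of the mean log2 ratio. The share was 0.561 of 280 probes, and its 95% interval of 0.5 to 0.62 includes 0.6, so the prediction was not met beyond its spread. The same sign was seen in 97.1% of these probes. A dye effect of the tested probe alone gives no reason for that. The signs therefore argue against it as the only source of these calls. The other probes were by selection dimmer than the tested probe, with a median difference in mean intensity of -2.58 on the log2 scale. What dimness alone does to the share of 0.561 was not tested. A dye effect on the size of the ratios, or one common to the probes of a gene, stays open for these calls. So does the change over time that the design names.

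At least 2-fold opposite ratios at all 4 times in different replicates were seen in 31 gene models, fewer than the 90.3 expected if the replicates were independent. The median share of the difference that lay in the Cy3 level was 0.81 (95% interval 0.782 to 0.911). This was above the 0.5 predicted if the 0 h samples differed between replicates. But these gene models were chosen for opposite ratios at all 4 times, and the 0 h channel is what those times share. That choice may itself favour Cy3. No share for unselected gene models is given beside it, so the test cannot decide. Of the 31, 3 had a saturated spot in replicate 1. The arrays of a replicate share a slide, so that slide and 0 h sample cannot be separated here. Of 62 other probes of these genes a share of 0.855 showed the same opposite signs (95% interval 0.742 to 0.931, or 0.758 to 0.952 with genes resampled). Noise of single probes predicted under 0.5, which both intervals exclude, so the share argues against it. The bound of 0.75 written against it was passed by the share but lies inside the first interval.

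The 48 h array of replicate 3 had small ratios, with a slope of 0.447 on the mean of 24 h and 72 h of that replicate, where the others had 1.02 and 0.889. It also had 542 outlier spots, against 3 to 32 on the other arrays. A compressed signal predicted a Cy3 slope under 0.9 on the other arrays of its slide. The slope was 0.966, below the range of 0.977 to 1.01 of the other 11 arrays but not under 0.9, so the test did not decide. No biological explanation was tested.

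Neighbouring loci were hypothesised to change together. At 96 h 15 adjacent pairs were called in 1 direction, where random placement gave a mean of 11.4 (permutation p = 0.17), so no excess was shown. The pair with the largest ratios was CHLRE_13g585500v5 and CHLRE_13g585550v5, at 4.10 ± 0.78 and 5.94 ± 0.61 (SD, n = 3), singled out after its values were seen.

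In replicate 1, 58 gene models were saturated in both channels on all 4 arrays and shared a mean log2 ratio of -1.23, a value set by the scanner limit and the normalization. They form the vertical line of points in the plot of replicate against replicate.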
